A study of Mus musculus with 5 samples.

How the data were processed

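Expression was measured in 5 samples of marrow erythroblasts on Illumina bead arrays. Per the labels' protocols, total RNA was extracted with a QIAGEN kit, checked on an Agilent Bioanalyser and turned into biotinylated cRNA with an Ambion MessageAmp kit. Groups and replicate numbers came from the sample titles and genotype labels, 2 arrays labelled Flvcr-deleted and 3 labelled wild-type. The labels name no slide, scan date or batch.

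The values used were those the authors deposited for each sample, taken to be on a log2 scale. Scale and normalization are read from the values, since the labels and file headers state neither. Every array ran from 6.35 to 15.06, with medians of 6.76, and shared the same distribution, as quantile normalization gives. The lowest values lie well above 0, as where background was not subtracted or a constant was added, and the values cannot tell which. The log base and the software are not given in the sources used here, so a log2 difference is one on the scale as read. No value was missing. A table of signals and detection p-values before normalization was not used here, because the names of its 10 columns match no sample's labels and columns were not assigned by order or by value. The planned analysis started from such signals with limma's neqc, so the same limma model was run on the deposited values in its place. Because detection p-values could not be used, a background floor was set from the values: the peak of all signals, 6.70, plus 1.64 times the spread of its lower side, 0.0823, which gives 6.83, a one-sided p of 0.05 if background is normal.

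Of 45281 probes, the platform annotation gave 34885 a unique gene symbol, 18 several and 10378 none, and probes with several or none were not named. A probe was kept if it lay above the floor on at least 2 arrays, which left 17690 probes, 15174 of them with a unique symbol. For each of the 10057 genes the kept probe of highest mean signal was used, and kept probes of opposite sign are named where they occur (Fdps, Gata1, Ift140, Lss and Rpl23, out of 56 named genes with several kept probes). Differences, labelled Flvcr-deleted minus labelled wild-type, were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with genotype as the only term, two-sided, on all 5 arrays (3 residual and 5.65 prior degrees of freedom). P-values were adjusted with the Benjamini-Hochberg method over all genes tested and called under 0.05.

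The 27 gene lists, fixed in advance, were heme synthesis, iron uptake and storage, heme breakdown and NRF2/BACH1 targets, globins, erythroid transcription factors, red cell membrane and skeleton, progenitor genes, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, ATF4 integrated stress response, p53 targets, DNA replication, mitosis, late erythroid organelle clearance and antioxidants, unfolded protein response, heat shock and proteasome, oxidative phosphorylation, glycolysis, cholesterol synthesis, interferon response, and markers of neutrophils, macrophages, B cells, T and NK cells, megakaryocytes, and mast cells, basophils and eosinophils. Older symbols were matched through a RefSeq gene table, except where a member's name is itself a current symbol. That exception was added after an initial run, in which Pigq and Eno1b had been taken as members of glycolysis. Fth1 and Ftl1, Foxo3, Sesn2 and Bpgm each belong to 2 lists, and no marker of another cell type belongs to another list. In the arrays labelled wild-type, 15 of 16 neutrophil, 15 of 17 macrophage, 5 of 7 B cell, 2 of 3 T and NK cell, 4 of 6 megakaryocyte and 7 of 8 mast cell, basophil and eosinophil markers lay above the floor on all 3 arrays. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted with Benjamini-Hochberg over the lists, and members were also adjusted over the list alone. Camera compares a list with all other genes, and fry asks only whether its genes move one way on balance. With an estimated correlation, camera's test also has only the 3 residual degrees of freedom, which raises its p-values whatever the correlation. For tests of explanations, a list's median was set against 10000 random lists of genes within 100 ranks of its members in mean signal, drawn anew in each refit. With all arrays, this was done for every list.

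The genes named are Flvcr1, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, up to 4 called members per list with the largest change, and always Hmox1, Alas2, Gata1, Klf1, Tfrc, Kit, Hba-a1, Hbb-b1 and Cdkn1a. Hbb-b1 was not analysed here. Slc4a1, Tsr1, Atf4, Ppp1r15a, Cars, Ddit3, Hspa5 and Bpgm were named after their values were seen. On simulated data of the same 10057 genes with 200 changed, the comparison recovered none at a log2 change of 0.5, 86% at 1 and 99% at 2, with 0, 4 and 7 false calls. The simulation has few changed genes, which makes its threshold stricter than that of the real data.

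Alternatives were normexp background correction (offset 50) followed by quantile normalization, no filter on dim probes, the mean of a gene's probes, every probe on its own, a mean-variance trend with robust prior, array weights, the replicate number as a block, other thresholds, an estimated correlation or fry for the lists, and leaving out each array. A floor on all 5 arrays, a stricter floor and cyclic loess on the deposited values were added after the data were seen. Figures were drawn with matplotlib 3.10.9.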

Results

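Total RNA from marrow erythroblasts, the nucleated precursors of red cells, of C57BL/6J mice was measured on 5 Illumina bead arrays. By genotype, 2 arrays are labelled Flvcr deleted and 3 wild type. Flvcr1, called Flvcr in the labels, encodes a heme exporter of the cell surface, and the series title concerns the part played by heme and the transcription factor GATA1 in erythroid differentiation. The design gives a single comparison, which asks which transcripts differ in erythroid cells after deletion of the gene. Each array gave a log2 signal for 45281 probes, and between 35.9% and 36.0% of them lay above the background floor. The shared distribution of the arrays makes these shares alike. Across probes, arrays of the same group correlated with r between 0.989 and 0.992 and arrays of different groups with r between 0.948 and 0.954, and the first principal component, with 84.9% of the variance, separated the groups. The number of arrays limits the precision of every value. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

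The Flvcr1 probe read 9.88 and 9.75 in the arrays labelled Flvcr-deleted and 8.16, 8.32 and 8.25 in the arrays labelled wild-type, as log2 signal. The means were 9.81 ± 0.10 (SD, n = 2) and 8.24 ± 0.08 (SD, n = 3), a log2 difference of 1.57 (SE 0.10) or 2.97-fold (limma, adjusted p = 1.34e-05). This signal was higher where the label says the gene is deleted, the opposite of a loss of signal. The other Flvcr1 probe was not above background on any array, with means of 6.67 and 6.71. Where the measured probe lies relative to the deleted part of the gene is not given in the sources used here, so it checks neither the deletion nor the labels. The groups are therefore named by their labels throughout, and every direction given here, labelled Flvcr-deleted relative to labelled wild-type, rests on those labels alone.

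In the arrays labelled Flvcr-deleted, 23 of 24 genes of ribosome biogenesis, 10 of 14 of glycolysis and 17 of 25 of the ATF4 stress response rose, while 11 of 13 genes of heme synthesis, 17 of 21 of the red cell membrane, 17 of 22 of mitosis and 16 of 26 of DNA replication fell. These lists passed with camera at the preset correlation, and their values lay between adjusted p = 0.0806 and adjusted p = 0.187 with an estimated correlation, where none passed. In the same arrays 6 of 16 neutrophil, 7 of 8 mast cell, basophil and eosinophil and 4 of 7 B cell markers fell. Of 10057 genes tested, 3962 (39.4%) changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 2199 of them higher and 1763 lower, with 468 higher and 488 lower by at least 2-fold. Among the largest rises, C2cd4a, a nuclear C2-domain protein, was at least 18.6-fold higher, with signals near the floor in the arrays labelled wild-type (log2 difference 4.25, SE 0.10, n = 2 and 3), Trib3, a pseudokinase induced by ATF4, 10.7-fold higher (3.42, SE 0.24) and Cdkn1a, the cell cycle inhibitor p21, 7.65-fold higher (2.94, SE 0.17). Among the largest falls, Prg2, the eosinophil major basic protein, was 11.1-fold lower (-3.47, SE 0.34) and Fn3k, fructosamine 3-kinase, 7.60-fold lower (-2.93, SE 0.10).

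The other genes of largest rise, each as log2 difference ± SE, were Ccnd2, the G1 cyclin D2 (2.90 ± 0.12), Nupr1, a stress-induced chromatin protein (2.73 ± 0.10), Psat1 of serine synthesis (2.71 ± 0.12), Chac1, which degrades glutathione (2.70 ± 0.14), F2r, a thrombin receptor (2.68 ± 0.17), the cytokine oncostatin M, Osm (2.59 ± 0.15), the tetraspanin Tspan14 (2.57 ± 0.11) and Bex4 (2.50 ± 0.17). Trgv4, a variable segment of the T cell receptor gamma locus, was not above background in the arrays labelled wild-type and was at least 11.6-fold higher in the others (adjusted p = 7.77e-07). The other genes of largest fall were the basophil and mast cell protease Prss34 (-3.06 ± 0.33), Ift140 of intraflagellar transport (-2.74 ± 0.09), Denn2b (-2.61 ± 0.11), Btrc, an F-box protein of a ubiquitin ligase (-2.44 ± 0.10), Pdzk1ip1 (-2.42 ± 0.12), the CDK4 and CDK6 inhibitor Cdkn2d (-2.40 ± 0.18), and the neutrophil granule genes Prtn3 (-2.99 ± 0.52), Elane (-2.66 ± 0.48), Ctsg (-2.65 ± 0.44) and Mpo (-2.50 ± 0.49). A bound of this kind sets the mean of the brighter group against the mean, in the dimmer one, of the floor or the probe's own signal, whichever is higher on each array, and 84 genes called higher and 61 called lower were not above background in the dimmer group. It also applies to C2cd4a, Nupr1 (at least 6.59-fold higher), Zmat3 (at least 1.64-fold higher) and Cd74 (at least 2.36-fold lower), which had 1 or 2 arrays of the dimmer group at or below the floor. Folds are ratios of signals that appear to hold background or an added constant, which would make them understate changes of dim genes. With normexp background correction of the deposited values Trib3 was 12.3-fold higher. With the mean of a gene's probes in place of the brightest probe, the differences of C2cd4a (2.48), Trib3 (2.38), Cdkn1a (1.79), Ccnd2 (1.88), Osm (1.51), Fn3k (-1.85), Ift140 (-1.37) and Btrc (-0.94) were smaller and still passed.

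Heme synthesis fell as a group, with 11 of 13 measured members lower, none higher and 2 not past the threshold, and a median log2 difference of -0.88 (camera, adjusted p = 1.02e-06; adjusted p = 0.0806 with an estimated correlation). The falls were largest for Ppox, protoporphyrinogen oxidase (-1.44 ± 0.10), Slc25a38, the mitochondrial glycine carrier (-1.35 ± 0.12), Uros, uroporphyrinogen III synthase (-1.26 ± 0.10), and Fech, ferrochelatase (-1.17 ± 0.10). Alas2, the erythroid enzyme of the initial step, fell by 0.91 (SE 0.11, adjusted p = 1.88e-04). In the list of iron uptake and storage, 4 of 18 members fell, 2 rose and 12 did not pass, with a median of -0.04 (camera, adjusted p = 0.265). No iron gene was higher without Flvcr-deleted replicate 2, and 1 was without Flvcr-deleted replicate 1, wild-type replicate 2 or wild-type replicate 3. Those that fell were the mitochondrial iron carrier Slc25a37 (-1.52 ± 0.11), the iron transporter Slc11a2 (-1.04 ± 0.14), the ferritinophagy receptor Ncoa4 (-0.98 ± 0.12) and the transferrin receptor Tfrc (-0.76 ± 0.11). Heme breakdown and NRF2 or BACH1 targets had 2 members higher, 4 lower and 14 not past the threshold of 20, with a median of -0.10 (camera, adjusted p = 0.301). Prdx1 (0.90 ± 0.16) rose, and Nqo1 (-0.89 ± 0.13), the biliverdin reductase Blvrb (-0.67 ± 0.10) and Gclm of glutathione synthesis (-0.57 ± 0.10) fell. Hmox1, which degrades heme and is induced by it, differed by -0.12 (SE 0.27, adjusted p = 0.795), within the spread of the arrays. Of 8 globin genes measured, none rose, 2 fell and 6 did not pass, with a median of -0.16 (camera, adjusted p = 0.102). The alpha globin gene Hba-a1 differed by -0.11 (SE 0.10, adjusted p = 0.432) at means of 14.71 and 14.83, near the highest signal on the arrays, 15.06. The theta globin genes Hbq1a (-0.75 ± 0.23) and Hbq1b (-0.50 ± 0.16) passed by little, and without Flvcr-deleted replicate 1 or 2 or wild-type replicate 1 or 3, neither passed, with adjusted p up to 0.144 for Hbq1a and 0.131 for Hbq1b. Adjusted over the list alone, the counts were 11 lower for heme synthesis, 2 higher and 4 lower for both the iron and the heme breakdown lists, and 0 for the globins.

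Erythroid transcription factors fell on balance, with 10 of 15 members lower, 2 higher and 3 not past the threshold. The median was -0.70 (camera, adjusted p = 0.00208; adjusted p = 0.187 with an estimated correlation). Klf3 (-2.27 ± 0.28), Sox6 (-2.26 ± 0.31) and Tal1 (-1.11 ± 0.10) fell most, Klf1, a master regulator of erythroid genes, fell by 0.79 (SE 0.10), and Bcl11a, a repressor of globin genes, rose (1.28 ± 0.13). Gata1 was lower by the brighter of its probes (-0.66 ± 0.11, adjusted p = 0.00138). Its other probe gave 0.41 (adjusted p = 0.126), and with the mean of both the difference was -0.13 and the call was lost (adjusted p = 0.462, against 6.18e-04 at the lowest of its alternatives). Without Flvcr-deleted replicate 2 or wild-type replicate 1, 1 transcription factor was higher in place of 2. Genes of the red cell membrane and its skeleton fell, with 17 of 21 lower, none higher and 4 not past the threshold. The median was -1.01 (camera, adjusted p = 7.43e-09; adjusted p = 0.119 with an estimated correlation). They included Kel of the Kell blood group (-2.10 ± 0.18), dematin, Dmtn (-1.76 ± 0.16), the actin-capping Tmod1 (-1.53 ± 0.12) and the adhesion molecule Icam4 (-1.49 ± 0.11), while the anion exchanger Slc4a1 differed by 0.03 and did not pass. The list of late erythroid organelle clearance and antioxidant genes had 19 of 29 members lower, 2 higher and 8 not past the threshold. The median was -0.64 (camera, adjusted p = 2.93e-06; adjusted p = 0.109 with an estimated correlation). Hagh (-1.82 ± 0.19), the ubiquitin-conjugating enzyme Ube2l6 (-1.56 ± 0.17), Trim10 (-1.20 ± 0.11) and Ranbp10 (-1.19 ± 0.19) fell most. Progenitor genes moved the other way, with 6 of 14 higher, 1 lower and 7 not past the threshold. The median was 0.22 (camera, adjusted p = 0.0173; adjusted p = 0.171 with an estimated correlation). Gata2 (1.39 ± 0.16), Myc (0.88 ± 0.11) and the stem cell factor receptor Kit (0.78 ± 0.14) rose, and Lyl1 fell (-0.84 ± 0.10). In the same arrays, 6 of 16 neutrophil markers fell (list median -0.97, or -0.43 without Flvcr-deleted replicate 1 and -0.47 without wild-type replicate 3; adjusted p = 0.175 with an estimated correlation). So did 7 of 8 mast cell, basophil and eosinophil markers (-1.23; adjusted p = 0.109 with an estimated correlation) and 4 of 7 B cell markers (-0.65; adjusted p = 0.280 with an estimated correlation). Adjusted over the list alone, 3 transcription factors were higher and 10 lower, 18 membrane genes were lower, 2 late genes were higher and 20 lower, and 6 progenitor genes were higher and 1 lower. The call of the progenitor list was lost when genes had to lie above the floor on all 5 arrays (median 0.59, adjusted p = 0.0710), and with the mean of a gene's probes the values for Sox6 (-0.74) and Kit (0.43) and the median of the transcription factors (-0.45) were smaller.

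Of 22 mitosis genes, 17 were lower, none higher and 5 did not pass (median -0.81; camera, adjusted p = 7.43e-09; adjusted p = 0.0806 with an estimated correlation), and of 26 DNA replication genes, 16 were lower, none higher and 10 did not pass. The median was -0.58 (camera, adjusted p = 3.33e-07; adjusted p = 0.0806 with an estimated correlation). The mitosis genes with the largest falls were the kinesin Kif23 (-1.45 ± 0.10), the spindle protein Nusap1 (-1.35 ± 0.10), the mitotic kinase Cdk1 (-1.26 ± 0.09) and Prc1 of the central spindle (-1.10 ± 0.15). Cyclin E2, Ccne2 (-1.35 ± 0.13), the ribonucleotide reductase subunit Rrm2 (-1.31 ± 0.10), Cdc6 of origin licensing (-1.06 ± 0.10) and DNA ligase 1, Lig1 (-0.93 ± 0.12), led the replication list. Neutrophil, mast cell, basophil and eosinophil, and B cell markers had list medians of -0.97, -1.23 and -0.65 in the same comparison (adjusted p = 0.175, 0.109 and 0.280 with an estimated correlation), and Ccnd2, a G1 cyclin outside both cell cycle lists, rose by 2.90 ± 0.12. Among p53 targets the changes went both ways, with 8 of 21 higher, 5 lower and 8 not past the threshold. The median was 0.05 (camera, adjusted p = 0.638). Cdkn1a (2.94 ± 0.17), cyclin G1, Ccng1 (1.11 ± 0.18), and the RNA-binding Zmat3 (0.86 ± 0.11) rose, and sestrin 1, Sesn1, fell (-1.49 ± 0.12). With adjustment over the list alone, 17 mitosis genes and 19 replication genes were lower, and 8 p53 targets were higher and 5 lower. Without Flvcr-deleted replicate 2, 5 p53 targets were higher and 3 lower, and 3 were lower without wild-type replicate 1 or 3. With the mean of a gene's probes, the differences of Nusap1 (-0.72), Cdk1 (-0.71) and Prc1 (-0.71) and the median of the replication list (-0.34) were smaller.

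Ribosome biogenesis rose, with 23 of 24 measured members higher, none lower and 1 not past the threshold, Tsr1 at -0.16. The median was 1.37 (camera, adjusted p = 4.11e-12; adjusted p = 0.0806 with an estimated correlation). Nop58, a core protein of box C/D ribonucleoproteins, rose by 2.00 ± 0.18, or 4.01-fold, Rrp12 by 1.94 ± 0.10, Mybbp1a by 1.81 ± 0.13 and Gar1, of box H/ACA ribonucleoproteins, by 1.78 ± 0.10. Mitochondrial ribosomal protein genes rose too, with 48 of 73 higher, 3 lower and 22 not past the threshold. The median was 0.62 (camera, adjusted p = 7.43e-09; adjusted p = 0.277 with an estimated correlation). Mrps18b (1.52 ± 0.14), Mrpl36 (1.40 ± 0.15), Mrps10 (1.18 ± 0.13) and Mrpl12 (1.15 ± 0.13) rose most. Of 50 cytosolic ribosomal protein genes, 14 were higher, 2 lower and 34 not past the threshold. The median was 0.19 (camera, adjusted p = 0.0152; adjusted p = 0.399 with an estimated correlation). Rplp0 (0.74 ± 0.10), Rpl30 (0.70 ± 0.10) and Rpl4 (0.57 ± 0.12) rose, and Rpl23 was lower by its brightest probe (-0.87 ± 0.18), while another Rpl23 probe was higher (0.62, adjusted p = 9.13e-04 among all probes kept) and the mean of its probes differed by -0.07 (adjusted p = 0.622). In oxidative phosphorylation, 21 of 68 genes were higher, 3 lower and 44 not past the threshold. The median was 0.16 (camera, adjusted p = 0.0205, and adjusted p = 0.442 with an estimated correlation). It lay inside the central 95% of matched random lists, -0.15 to 0.18. Cox5a (0.85 ± 0.11), Atp5g2 (0.72 ± 0.10), Ndufa12 (0.71 ± 0.13) and Ndufa8 (0.64 ± 0.10) rose most. Adjusted over the list alone, the counts were 23 higher for ribosome biogenesis, 51 higher and 3 lower for mitochondrial ribosomal proteins, 14 higher and 2 lower for cytosolic ones, and 19 higher and 3 lower for oxidative phosphorylation. Without Flvcr-deleted replicate 2 the cytosolic list lost its call (adjusted p = 0.0572, 7 genes higher) and no mitochondrial ribosomal protein gene was lower. Of the latter 1 was lower without wild-type replicate 1 or 3, and 1 cytosolic gene was lower whichever array was left out. Without Flvcr-deleted replicate 1, Rpl23 was at -0.53. The oxidative phosphorylation list lost its call without Flvcr-deleted replicate 1 (adjusted p = 0.0531, 10 genes higher and 1 lower), without wild-type replicate 2 (0.0929), with the floor required on all 5 arrays (0.0516) and with fry (0.0605), and with the mean of a gene's probes Mybbp1a (1.05), Gar1 (1.17) and Rpl30 (0.40) were smaller.

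Targets of ATF4, the transcription factor of the integrated stress response, rose on balance, with 17 of 25 higher, 2 lower and 6 not past the threshold. The median was 0.55 (camera, adjusted p = 6.19e-05; adjusted p = 0.171 with an estimated correlation). Trib3, Nupr1, Psat1 and Chac1 rose by 3.42, 2.73, 2.71 and 2.70, and Atf4 itself by 0.55. The phosphatase subunit Ppp1r15a, which ends the response, was lower (-1.83), as was the cysteinyl-tRNA synthetase Cars (-0.97), and Ddit3 did not pass (0.03). The unfolded protein response list had 9 of 15 members higher, none lower and 6 not past the threshold. The median was 0.44 (camera, adjusted p = 1.70e-04; adjusted p = 0.171 with an estimated correlation). Its transcription factor Xbp1 (1.80 ± 0.12) and the endoplasmic reticulum proteins Sdf2l1 (1.24 ± 0.15), Pdia4 (1.10 ± 0.19) and Pdia3 (0.96 ± 0.11) rose most, while the chaperone Hspa5 differed by 0.17 and did not pass. Heat shock and proteasome genes had 10 of 17 higher, 1 lower and 6 not past the threshold. The median was 0.40 (camera, adjusted p = 4.53e-04; adjusted p = 0.109 with an estimated correlation). The mitochondrial chaperonins Hspd1 (1.62 ± 0.11) and Hspe1 (1.31 ± 0.20) and the co-chaperone Bag3 (1.50 ± 0.10) rose, and the co-chaperone Dnajb1 fell (-0.75 ± 0.12). Adjusted over the list alone, 17 ATF4 targets were higher and 2 lower, 10 unfolded protein response genes were higher, and 11 heat shock and proteasome genes were higher and 1 lower. The median of the unfolded protein response list was 0.69 without Flvcr-deleted replicate 2 and 0.80 with the floor required on all 5 arrays.

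Glycolysis rose, with 10 of 14 members higher, 1 lower and 3 not past the threshold. The median was 0.86 (camera, adjusted p = 6.19e-05; adjusted p = 0.187 with an estimated correlation). Lactate dehydrogenase A, Ldha, rose by 1.92 ± 0.10, or 3.79-fold, Aldoa by 1.81 ± 0.11, Pfkp by 1.80 ± 0.11 and Pgk1 by 1.39 ± 0.12. Bpgm, which makes the bisphosphoglycerate of red cells and is also in the late erythroid list, was not above background in the arrays labelled Flvcr-deleted and was at least 1.40-fold lower there. Cholesterol synthesis had 9 of 15 members higher, none lower and 6 not past the threshold. The median was 0.41 (camera, adjusted p = 3.14e-04; adjusted p = 0.171 with an estimated correlation). Farnesyl diphosphate synthase, Fdps (1.54 ± 0.26), Msmo1 (1.40 ± 0.09), lanosterol synthase, Lss (1.22 ± 0.11), and Hsd17b7 (1.05 ± 0.12) rose most. With adjustment over the list alone, 10 glycolysis genes were higher and 1 lower, and 10 cholesterol genes were higher. For Fdps, Lss and Ift140, a further probe close to the floor had a difference of the opposite sign that did not pass. With the mean of a gene's probes Pfkp (1.20), Pgk1 (0.71), Fdps (0.76) and Lss (0.55) were smaller.

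Markers of other marrow cells were lower or did not pass, with exceptions named here. Mast cell, basophil and eosinophil markers fell, with 7 of 8 lower, none higher and 1 not past the threshold (median -1.23; camera, adjusted p = 1.49e-04; adjusted p = 0.109 with an estimated correlation), among them Prg2, Prss34, the histidine decarboxylase Hdc (-1.87 ± 0.14) and the mast cell carboxypeptidase Cpa3 (-1.24 ± 0.16). Neutrophil and granulocyte precursor markers fell, with 6 of 16 lower, none higher and 10 not past the threshold. The median was -0.97 (camera, adjusted p = 6.42e-04; adjusted p = 0.175 with an estimated correlation). Myeloperoxidase, Mpo, read 12.34 and 10.25 in the arrays labelled Flvcr-deleted and 13.69, 14.13 and 13.56 in those labelled wild-type. B cell markers fell, with 4 of 7 lower, none higher and 3 not past the threshold. The median was -0.65, or -0.54 with genes not above background at their bound (camera, adjusted p = 0.00149; adjusted p = 0.280 with an estimated correlation). By the probes used, Cd79b, Vpreb3 and Igll1 were not above background in the arrays labelled Flvcr-deleted and were at least 2.51-fold, 2.40-fold and 1.45-fold lower there, and Cd74 fell by 1.27 ± 0.11. Another Cd79b probe lay above the floor in Flvcr-deleted replicate 1 (6.92) and had a smaller fall (-0.79; limma, adjusted p = 0.00434 among all probes kept). Macrophage and monocyte markers had 2 of 17 lower, the lysozymes Lyz1 (-1.42 ± 0.29) and Lyz2 (-1.23 ± 0.21), none higher and 15 not past the threshold. The median was -0.37 (camera, adjusted p = 0.0206; adjusted p = 0.441 with an estimated correlation). Of 3 T and NK cell markers measured, Nkg7 fell (-1.80 ± 0.29) and 2 did not pass. The median was -0.07, or -0.01 at the bound (camera, adjusted p = 0.502). Of 6 megakaryocyte and platelet markers, Gp5 rose (1.42 ± 0.11), Gp9 (-2.07 ± 0.10) and Vwf (-1.03 ± 0.11) fell and 3 did not pass. The median was -0.002 (camera, adjusted p = 0.457). Interferon response genes fell, with 5 of 14 lower, none higher and 9 not past the threshold (median -0.33; camera, adjusted p = 0.00796; adjusted p = 0.228 with an estimated correlation), among them Usp18 (-1.57 ± 0.21), Irf9 (-0.99 ± 0.10), Rsad2 (-0.93 ± 0.20) and Irf7 (-0.88 ± 0.14). Adjusted over the list alone, the numbers lower were 7 for mast cells, basophils and eosinophils, 6 for neutrophils, 5 for B cells, 2 for macrophages, 1 for T and NK cells and 5 for interferon, and 1 megakaryocyte marker was higher and 2 were lower.

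The size of several of these marker values rested on 1 array. Without Flvcr-deleted replicate 2, Prtn3 was at -1.90, Elane at -1.64, Ctsg at -1.73, Mpo at -1.46 and Rsad2 at -0.59, all still past the threshold. The neutrophil list had a median of -0.43 without Flvcr-deleted replicate 1 and -0.47 without wild-type replicate 3, with its call kept, and 10 of its members were lower without wild-type replicate 2. The macrophage list lost its call without Flvcr-deleted replicate 2 (median -0.11, adjusted p = 0.134), without wild-type replicate 1 (-0.14, 0.0594) and with fry (0.195), and stood at -0.23 without wild-type replicate 2 and at -0.61, with 10 members lower, without wild-type replicate 3. With 4 members lower, its call was kept without Flvcr-deleted replicate 1. The interferon list stood at -0.21 without wild-type replicate 1, and 1 of its members was higher without that array or Flvcr-deleted replicate 1. With a mean-variance trend and robust prior, Prtn3 (adjusted p = 0.0733), Elane (0.0786), Ctsg (0.0623) and Mpo (0.0918) did not pass, the highest values over their alternatives, whose lowest were 1.05e-05, 7.95e-06, 3.87e-06 and 2.44e-05. With the mean of a gene's probes Lyz2 (-0.75) and Cpa3 (-0.75) were smaller, and without a filter on dim probes, which adds dim members, the medians were -0.19 for B cells, -0.59 for mast cells, basophils and eosinophils and -0.14 for interferon. With the floor required on all 5 arrays, the median for mast cells, basophils and eosinophils was -2.46.

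**Figure D1:**
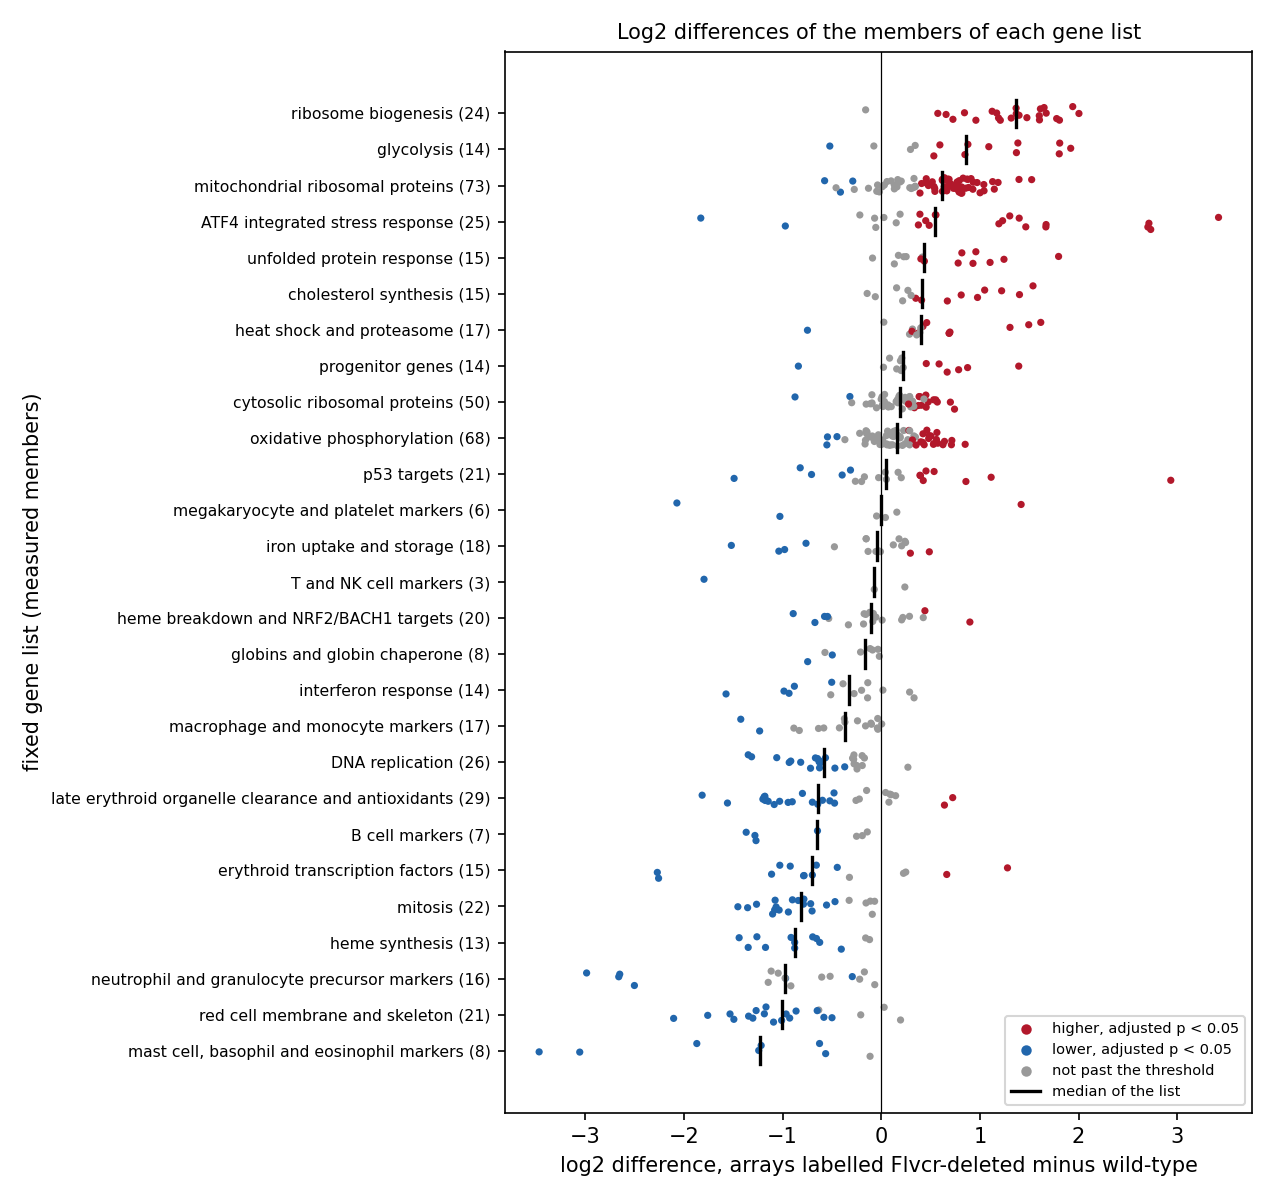
Log2 differences, arrays labelled Flvcr-deleted minus arrays labelled wild-type, of the measured members of the 27 gene lists, 1 point per gene, colored by whether the gene passed an adjusted p under 0.05, with the median of each list as a black bar. Medians run from -1.23 for mast cell, basophil and eosinophil markers to 1.37 for ribosome biogenesis.

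**Figure D2:**
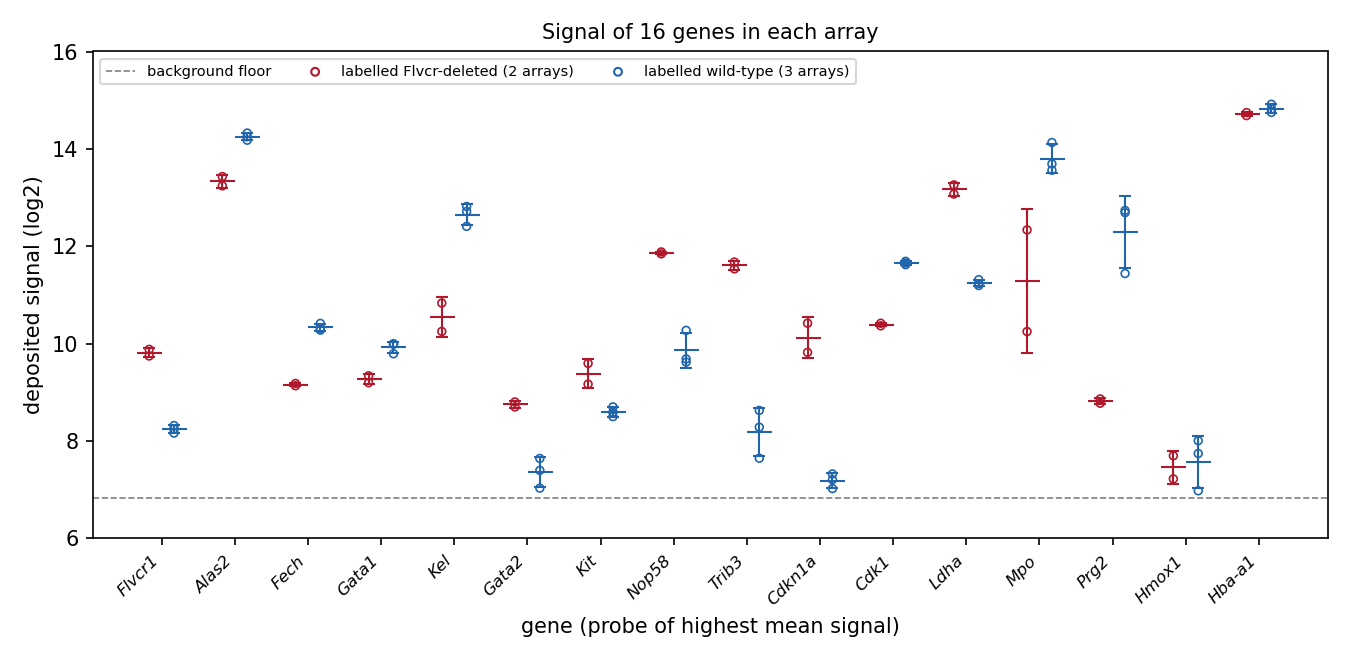
Deposited log2 signal of 16 genes in each of the 5 arrays, with open circles for arrays, horizontal bars for group means, error bars of 1 SD and a dashed line at the background floor. The genes were chosen after their values were seen. The signals of Flvcr1 are higher in both arrays labelled Flvcr-deleted (9.88 and 9.75) than in the arrays labelled wild-type (8.16, 8.32 and 8.25), and those of Hmox1 overlap between groups.

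Over all genes tested, the median log2 difference was 0.01, a value largely set by the shared distribution of the arrays. A change of all transcripts together could therefore not be seen, and rises and falls are relative to other genes. The groups did not overlap in 3960 of the 3962 genes called. Groups of 2 and 3 did not overlap for 59.1% of all genes tested, against 20% by chance. Of the 27 gene lists, 21 passed with camera at the preset correlation, 10 higher and 11 lower, and 0 passed with an estimated correlation, where 8 had an unadjusted p under 0.05. For mitosis the estimated correlation was 7.14e-04 and for heme synthesis -0.06, below the preset 0.01. Their unadjusted camera p still rose, from 1.06e-09 to 0.00688 and from 2.27e-07 to 0.0119. Neither loss therefore comes from a higher correlation, while other lists had estimates up to 0.513 (B cell markers). The self-contained test fry called 21, of which 19 were also called by camera.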

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

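The alternatives were fixed before the data were examined, except the floor on all 5 arrays, the stricter floor and cyclic loess, which were chosen after. They were planned for signals before normalization but run on the deposited values. The normexp correction is therefore a further correction of values that already shared a distribution. The floor took the place of a planned filter on detection p-values. Against 3962 genes called, 956 passed with a change of at least 2-fold required as well and 6263 probes passed when every probe was tested on its own. The former adds a criterion. The latter counts several probes per gene and adds 2516 probes without a unique gene symbol, of which 381 were called higher and 421 lower. Of the 21 lists called, 0 passed with an estimated correlation in camera (8 at an unadjusted p under 0.05) and 19 with fry, and for each of the 21 that adjusted p was the highest of all alternatives run. Leaving out 1 array gave between 2997 and 3874 genes, between 19 and 21 lists and a Flvcr1 difference between 1.50 and 1.64; where this left 1 array labelled Flvcr-deleted, it was assumed to vary like the others. An adjusted p under 0.10 gave 4598 genes. The other refits gave between 3601 and 4236 genes, between 18 and 22 lists and a Flvcr1 difference between 1.55 and 1.71, always past the threshold. In each refit per gene, all genes called there and with all arrays kept their direction. With the replicate block, 4236 genes, 21 lists and a Flvcr1 difference of 1.57 passed. Wild-type replicate 3 shares its number with no other array, so the block takes it up and the differences rest on the remaining arrays. The median of the red cell membrane list was -1.17 both with the block and without wild-type replicate 3. Deviations of same-numbered arrays correlated at -0.03 and 0.10. These values cannot show or exclude pairing, because the 2 arrays labelled Flvcr-deleted deviate by equal and opposite amounts. Hmox1 alone among named genes gained a call with the block (-0.42, adjusted p = 0.0127, range over its alternatives 0.0127 to 0.953). Calls gained elsewhere were the globin list with no filter (0.0279) and without wild-type replicate 2 (0.0361), and iron (0.00204) and megakaryocyte (0.0292) lists with fry; without a filter Hbq1a (0.0760) and Hbq1b (0.0658) lost theirs, and the cause was not tested. Not run were median scaling, cyclic loess or no background correction from signals before normalization and detection p filters, which need the table not used here, and a slide block, since no slide is given. Signals near the floor limit the folds of dim genes, and those near the top of the scale the differences of globins. The latter may also hold for the brightest genes of other lists. The highest means in the arrays labelled wild-type were 15.02 for cytosolic ribosomal proteins, 14.99 for the late erythroid list and 14.71 for the membrane list.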

Other observations

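The lists of aminoacyl-tRNA synthetases and of serine, one-carbon and polyamine synthesis, both tests on the Flvcr1 probe, the tests of a smaller share of other cell types and of the lists of neutrophil, macrophage, B cell and mast cell markers, the matched random lists within each alternative and the test on the cell cycle lists were chosen only after results were seen. Genes of serine, one-carbon and polyamine synthesis were higher in the arrays labelled Flvcr-deleted, with 8 of 9 higher and 1 lower (median log2 difference 1.33; limma's camera, adjusted p = 4.00e-05 over 2 lists; adjusted p = 0.0426 with an estimated correlation). Psat1 and Phgdh of serine synthesis rose by 2.71 ± 0.12 and 1.67 ± 0.11, spermidine synthase, Srm, by 2.48 ± 0.11, the reduced folate carrier Slc19a1 by 2.38 ± 0.11 and Mthfd1 of folate metabolism by 1.33 ± 0.12, while ornithine decarboxylase, Odc1, fell (-0.43 ± 0.12). Of 30 aminoacyl-tRNA synthetase genes, 19 rose, 2 fell and 9 did not pass (median 0.51; camera, adjusted p = 1.53e-04; adjusted p = 0.113 with an estimated correlation). Wars (1.69 ± 0.11), Lars (1.41 ± 0.11), Rars (1.39 ± 0.16) and Eprs (1.25 ± 0.16) rose most, and Cars (-0.97 ± 0.16) and Farsa (-0.30 ± 0.10) fell. Both lists share members with the ATF4 list and were chosen from these data, so their counts are not independent evidence of a direction.

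The Flvcr1 probe was higher by 1.57 in the arrays labelled Flvcr-deleted. An exchange of the genotype labels between the groups and a probe outside the deleted part of the gene cannot be told apart with this value, because no other gene is set by the labels and the position of the probe is not given. A greater abundance of a transcript that lacks the deleted part may also give this value, and was not tested. If the labels were exchanged, every direction reported would turn.

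Lower membrane and late erythroid lists with a higher progenitor list form a pattern for which a less mature mixture of erythroblasts in the arrays labelled Flvcr-deleted is a candidate explanation. More neutrophils, macrophages, B cells or mast cells, basophils and eosinophils in those arrays would raise their 4 lists. None lay above the central 95% of matched random lists, the highest value over all refits being the 10.1th percentile (macrophages without Flvcr-deleted replicate 2). These lists were chosen after their medians were seen to be lower, so this outcome was known and adds nothing to those falls. Against a trend with signal level left by the authors' normalization, 3 of 3 lists tested (membrane, late erythroid and ribosome biogenesis) had medians outside the central 95%. Cells of another type remain open for megakaryocytes and for T and NK cells: the highest of all 6 lists lay at the 53.5th percentile, but that list, of megakaryocytes, went both ways (Gp5 at 1.42, Gp9 at -2.07), the T and NK list had 3 measured members, and the T cell segment Trgv4 was at least 11.6-fold higher. A smaller share of other cell types alone would raise erythroid transcripts, whereas the membrane list had a median of -1.01. That fall was known when the test was chosen, and a smaller share may still occur along with it. Prg2 averaged 8.82 in the arrays labelled Flvcr-deleted against 12.29 in the arrays labelled wild-type. Mpo was at -2.50, or -1.46 without Flvcr-deleted replicate 2. Its call was lost with a mean-variance trend (limma, adjusted p = 0.0918, range over its alternatives 2.44e-05 to 0.0918). The labels name no sort or gate. The less mature mixture remains open, with the membrane and late lists below their matched lists and the progenitor median above its own, at the 98.3th percentile, but inside that range without wild-type replicate 1 (97.1th) or wild-type replicate 3 (97.2th), and so does an untested effect of the genotype within cells of the same stage. Not every gene went with a less mature mixture. The membrane gene Slc4a1 did not pass, 7 of 14 progenitor genes did not pass and Lyl1 fell (-0.84). The globin list was not called (median -0.16; camera, adjusted p = 0.102), at signals partly near the top of the scale.

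The DNA replication and mitosis lists were lower in the arrays in which neutrophil, mast cell, basophil and eosinophil, and B cell markers were lower too, with list medians of -0.97, -1.23 and -0.65. A less mature mixture would leave these lists level or higher, since early erythroblasts divide more than late ones, but the mitosis median was -0.81 against a central 95% of -0.25 to 0.29 in matched lists, and the replication median was -0.58 against -0.38 to 0.36. Both lay below their matched range in all 14 refits, the replication median by little with the mean of a gene's probes (-0.34 against -0.33 to 0.33). If that premise holds, which was not tested here, the mixture may not account for this part. The test was chosen after both medians were seen to be lower, and the refits reuse the same arrays, so it adds nothing to those falls. A smaller share of dividing cells of other types and an effect of the genotype on the cell cycle were not tested and remain open, and cell cycle regulators went both ways, with the inhibitor Cdkn1a and the cyclin Ccnd2 higher by 2.94 and 2.90 and the inhibitor Cdkn2d at -2.40.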
